A study of Mus musculus with 37 samples.

How the data were processed

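Single-nucleus RNA counts of mouse brain were taken as deposited: UMI counts per gene and nucleus in 3 tables, 1 of all hippocampal nuclei at 7 months, 1 of hippocampal astrocyte nuclei over a time course and 1 of cortex astrocyte nuclei. The nuclei in each table are those the authors kept, and the astrocytes of the last 2 tables were chosen by the authors. In the all-nuclei table every nucleus had at least 401 genes with a UMI. The submitters' processing notes name Cell Ranger 2.1.1, Seurat 3.0 and the genome mm10. Expression was compared as raw counts summed per library or as CPM, counts scaled to a fixed library total adjusted by the TMM factors of edgeR. Shares of nuclei and UMIs per nucleus were compared as well. UMIs per nucleus were pooled over all nuclei of a class and genotype, with no term for library, scheme or depth. Libraries with more nuclei weigh more in them.

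Of the 37 labelled libraries all but 1 were used, that 1 a WT library of 13-14 months. Genotype was read from the strain label, which names a C57BL strain for WT and 5xFAD for the others. The labels do not state littermate controls. A genotype difference here can therefore also be a difference of strain or colony. The 7-month comparison used 5 wild-type (WT) and 4 5xFAD libraries with 52724 nuclei. Their titles follow 3 naming schemes, N (WT 1, 5xFAD 1), HIP (WT 2, WT 3, 5xFAD 2) and HipR (WT 4, WT 5, 5xFAD 3, 5xFAD 4). The column names of this table tag N and HIP with NP40 and HipR with EZ, each scheme with its own batch tag. The schemes of the 7-month table therefore also mark preparation tag and batch. WT 1 and WT 3 carry the same mouse number, and their columns share an animal tag followed by R and L, so they are likely parts of 1 mouse. Separate animals are not stated for all libraries. The 5 WT are therefore libraries rather than animals, and p-values measure spread between libraries. The astrocyte time course used 23 libraries, 3 WT and 3 5xFAD at 1.5 months, 2 and 2 at 4-5 months, 2 and 2 at 7-8 months, 1 and 1 at 10 months, 3 and 2 at 13-14 months, and 2 WT at 19.6 months. Of the 1.5-month libraries 4 carry the tag 2m in their titles and 8w in their columns, and the labelled age of 1.5 months was used in the slopes, which were not refitted with the other age. Its schemes were HIP (8 libraries, 2468 nuclei), HipR (8, 7926 nuclei) and M (7, 8010 nuclei), with median depths per library of 664.0 to 732.5, 640.0 to 796.0 and 273.0 to 601.0 UMIs. The 4 HipR libraries of the 7-month table also occur in the time-course table, where only 5995 genes have a count above 0 in them, and were left out of the time-course fits. The cortex comparison used 2 and 2 libraries (7 and 10 months, 6312 nuclei, median depths 337.0 to 524.5 UMIs). Total UMIs per library ran from 3967757 to 12216892 in the 7-month table. The groups hold 4 labelled WT samples at 13-14 months, of which 3 were used. Columns of 2 library sets with 3970 nuclei, 2643 in the all-nuclei table and 1327 in the time-course table, were not used here because no sample label matched them.

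Nuclei of the 7-month table were normalised to 10000 counts, log-transformed, and clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components and 20 neighbours, using leidenalg 0.10.2 at resolution 1 on a graph of shared neighbours. A cluster was named after a fixed marker list when at least 3 markers were 1.5-fold over other nuclei at 10 CPM or more, and left unnamed when its median Scrublet score passed 0.1. Class names are labels by markers, so astrocyte here means astrocyte-like. All 5344 nuclei that the authors' astrocyte table shares with the all-nuclei table fell into the astrocyte-like clusters, which held 5488 nuclei in those libraries. A class needed 20 nuclei in a library.

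Counts were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood fit, TMM, filterByExpr), naming scheme as an additive term, Benjamini-Hochberg adjustment and a threshold of 0.05 on adjusted p. All tests were 2-sided. Time-course groups were genotype by age bin plus scheme, and slopes came from a fit of scheme, genotype, age and their product, given per 10 months. The cortex fit held genotype alone and the region fit held the animal. DESeq2 1.42.0 was the other tool, and limma 3.58.1 ran camera with a preset correlation of 0.01 and with a correlation estimated per list, for lists with at least 3 measured genes. Of 20 comparisons fitted across genes, each was adjusted on its own.

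The 27 fixed lists began with the transgene cassette, pan-reactive, A1 and A2 astrocyte lists, a disease-associated astrocyte list named in the study's own record, astrocyte homeostasis, cholesterol synthesis, lysosome and endosome, complement, antigen presentation (MHC1) and interferon response. The others were disease-associated and homeostatic microglia, disease-associated oligodendrocytes, myelin, synapse, immediate early, heat shock, nuclear oxidative phosphorylation, mitochondrial transcripts, cytoplasmic ribosome, nuclear long non-coding RNA, sex-linked genes, and markers of neurons, oligodendrocytes, microglia and vessels. The lists, tests, other settings and the rule for genes named in the text were set before the data were examined, while the limits for naming clusters were not part of that plan. The naming rule names App and Thy1, fixed genes of astrocytes, microglia and oligodendrocytes, up to 10 genes up and 10 down per test, and per list up to 4 called members or, with none called, 2 members. Some genes that it names are not reported here. Genes in fits with age or scheme terms were picked by adjusted p, and those of the cortex and region tests by fold change among genes whose groups do not overlap.

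Shares of nuclei per class were compared by exact permutation of the 9 libraries (126 splits, smallest p possible 0.00794). These splits take WT 1 and WT 3 as separate animals, and with them as 1 animal the smallest possible p would be larger. Shares of nuclei with a UMI of a gene were counted after thinning each nucleus to 600 UMIs, and the time course used a sign-flip test over 10 matched sets. Where a group had 0 counts a bound is given from a floor of 3 counts, and with 1 to 3 counts a ratio with its 95% counting interval. Gene positions are 1-based on GRCm38 (mm10) from GENCODE vM21. Symbols were taken from the tables. Other versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3, on 1 thread.

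A self-test drew negative binomial counts with the gene means and library totals of each table and a fixed spread. It changed known genes by 1.5, 2 or 4-fold and ran the same fits. All genes and all 7-month classes shared 1 spread and no scheme effect was drawn, so recovery in the data may be lower. The recovered percent of changed and tested genes at 2 and 4-fold was 68.4 and 100.0 in astrocytes, 53.1 and 97.1 in microglia, 77.8 and 100.0 in oligodendrocytes, 18.8 and 87.1 in their precursors, 80.0 and 100.0 in granule neurons, 85.2 and 100.0 in pyramidal neurons, 75.0 and 100.0 in inhibitory neurons, and 63.0 and 100.0 in endothelial nuclei. In the time course it was 64.2 and 94.5 for the mean difference, 30.2 and 80.0 at 1.5 months, 3.8 and 43.6 at 4-5 months, 7.5 and 40.0 at 7-8 months, 13.2 and 69.1 at 13-14 months, 4.1 and 46.3 for late minus 1.5 months, 67.8 and 96.2 for the WT slope, 35.6 and 90.6 for the 5xFAD slope, and 15.4 and 77.2 for the slope difference. Cortex reached 3.7 and 61.1, region 38.6 and 93.0, and region by genotype 0.0 and 19.1. At 1.5-fold the highest share was 54.7 percent, in pyramidal neurons, and astrocytes reached 32.6 percent.

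Thy1, whose promoter drives the transgenes, separated the genotypes within every scheme of the 7-month astrocytes (102.9 against 299 CPM in N, 72.45 and 96.02 against 213.2 in HIP, 252.2 and 262.9 against 571 and 613.6 in HipR). A check of sex-linked genes for mixed-up samples found 0 libraries that differed from the rest.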

Results

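Astrocyte nuclei of the hippocampus at 7 months carried more transcripts of reactive and complement genes in 5xFAD than in WT (n = 4 and 5 libraries, mean ± SD CPM, log2 differences of the edgeR fit with standard errors, SE). Serpina3n rose 9.94-fold, from 9.96 ± 2.49 to 113 ± 45.6 CPM (log2 3.31, SE 0.25, edgeR adjusted p = 1.02e-09). Osmr, a receptor of the interleukin 6 family, rose 7.37-fold from 16.5 ± 8.15 to 108 ± 51.2 CPM (2.88, SE 0.23). Vim, an intermediate filament gene, rose from 125.5 ± 35.8 to 479 ± 178 CPM (1.9552, SE 0.16). Gfap, the filament gene typical of astrocytes, rose from 1794 ± 583 to 4821 ± 822 CPM (1.56, SE 0.15, edgeR adjusted p = 1.66e-08). The complement gene C4b rose 3.08-fold, from 156.5 ± 19.3 to 470.4 ± 101 CPM (1.62, SE 0.14, edgeR adjusted p = 8.67e-09). The 2 groups did not overlap for any of these 5 genes. Each direction was the same within the 3 naming schemes (N, HIP, HipR), with Serpina3n 4.27, 3.05, 3.19, Osmr 2.90, 2.95, 2.80, Vim 2.38, 2.14, 1.73, C4b 1.64, 1.75, 1.55 and Gfap 1.92, 1.27, 1.58.

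More genes rose in the same astrocyte nuclei, the next 6 without overlap of the groups. Sbno2 rose from 27.6 ± 9.74 to 143 ± 41.5 CPM (log2 2.42, SE 0.19), Ggta1 from 36.3 ± 18.6 to 156.5 ± 23.2 (2.1029, SE 0.20) and Aspg from 16.9 ± 6.01 to 81.0 ± 26.6 (2.23, SE 0.24). Serping1, an inhibitor of complement C1, rose from 10.99 ± 4.33 to 68.1 ± 27.1 (2.39, SE 0.28, edgeR adjusted p = 1.2e-06). Gsn rose from 84.5 ± 33.2 to 207 ± 42.8 CPM (1.23, SE 0.17) and Ifi27 from 204 ± 27.4 to 370.3 ± 41.7 (0.81, SE 0.14). The lysosomal gene Ctsd rose by log2 0.96 (SE 0.16) and Csmd1 by 0.78 (SE 0.14). Thy1, whose promoter drives the transgenes, rose from 157 ± 92.3 to 424 ± 198 CPM (1.27, SE 0.14). App was at log2 -0.01 (edgeR adjusted p = 0.991).

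Transcripts typical of microglia also rose in the astrocyte nuclei. C1qa went from 26.6 ± 18.5 to 138 ± 43.5 CPM (log2 2.07, SE 0.19), Tyrobp from 10.3 ± 6.8 to 72.8 ± 30.2 (2.63, SE 0.24) and Trem2 from 8.52 ± 4.11 to 43.9 ± 9.54 (2.36, SE 0.29, edgeR adjusted p = 3.44e-06). C1qc rose by 1.70 (SE 0.27). Cst7 had 0 counts in WT and 125 in 5xFAD, at least 40.1-fold. In UMIs per nucleus the astrocyte rise was 1.48 times the rise in granule neuron nuclei for C1qa, 1.19 for Tyrobp, 1.37 for Trem2, 1.69 for Cst7, 1.87 for Ctsd, 2.38 for B2m, 1.79 for H2-D1 and 0.77 for Thy1. It was 7.55 times for Serpina3n, 14.0 for Vim, 12.5 for C4b, 39.9 for Ggta1, 101 for Osmr and 10.0375 for Gfap. Of the 136 genes that rose in astrocytes, 31 rose less than 3 times as much as in granule neurons, 28 of them with a higher level in microglia, and 105 rose more or had no rise in granule neurons.

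Upf2, Otc, Pcyt2 and Acss2 were lower in 5xFAD astrocyte nuclei. Upf2, a factor of nonsense-mediated decay, fell from 286.5 ± 63.5 to 74.8 ± 45.1 CPM (log2 -1.91, SE 0.20, edgeR adjusted p = 1.39e-07). Otc, an enzyme of the urea cycle, fell from 103 ± 23.8 to 27.4 ± 9.79 (-1.72, SE 0.21, edgeR adjusted p = 2.41e-06). Both did so without overlap and within each scheme (Upf2 -2.94, -2.15, -1.69, Otc -2.87, -1.86, -1.61). In time-course astrocytes of later ages Upf2 was at -0.26 (interval -0.98 to 0.46). Pcyt2, of phosphatidylethanolamine synthesis, fell from 911 ± 160 to 485 ± 65.6 CPM (-0.85, SE 0.14). Acss2, which makes acetyl-CoA, fell from 117 ± 21.6 to 50.9 ± 12.6 (-1.06, SE 0.18). For both the groups did not overlap. Hba-a1 fell by log2 -1.14 (SE 0.20), C030018K13Rik by -0.89 (SE 0.17), Gm12394 by -1.86 (SE 0.36, edgeR adjusted p = 0.00196). The amino acid transporter gene Slc7a10 fell from 531.5 ± 100 to 346 ± 94.5 CPM (-0.66, SE 0.14). Apoe was at log2 0.19 (SE 0.18, edgeR adjusted p = 0.693), Clu at 0.55 (0.0766), Cst3 at 0.42 (0.202), Slc1a2 at -0.00 (0.995) and Slc1a3 at 0.21 (0.552).

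Calls of 12 named genes in astrocytes were lost without some library. Ctsb rose by log2 0.75 (SE 0.15, edgeR adjusted p = 0.00292, 0.0825 without 5xFAD 2, 0.000303 to 0.647 over alternatives). Fkbp5 rose by 1.41 (edgeR adjusted p = 0.00463, 0.0862 without 5xFAD 2, 3.03e-05 to 0.235). H2-D1 rose by 0.73 (edgeR adjusted p = 0.0141, 0.107 without WT 4, 0.00903 to 0.855) and B2m by 0.63 (0.0155, 0.083 without WT 4, 0.00792 to 0.9). Bst2 rose by 1.16 (edgeR adjusted p = 0.0282, 0.356 without 5xFAD 4, 0.00698 to 0.356) and Fos by 1.18 (0.0124, 0.213 without 5xFAD 2, 0.000188 to 0.287). Nrg3 rose by 0.69 (edgeR adjusted p = 0.00705, 0.0655 without WT 5, 0.000637 to 1) and Kcnip4 by 0.60 (0.0242, 0.164 without WT 5, 0.00107 to 1). Srp54b fell by -1.0048 (edgeR adjusted p = 0.00196, 0.0799 without WT 5, 0.000216 to 0.592) and Etv4 by -0.84 (0.00301, 0.0551 without 5xFAD 2, 0.000274 to 0.29). Msmo1, of cholesterol synthesis, fell by -0.75 (edgeR adjusted p = 0.0226, 0.163 without WT 5, 0.00102 to 0.972) and Pdgfrb by -0.70 (0.0303, 0.279 without 5xFAD 2, 0.00541 to 0.443).

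Of 7910 genes tested in astrocytes with edgeR 176 changed, 136 up and 40 down, 117 did with DESeq2 and 30 with no naming scheme term. Of the 176, 167 had the same direction within all 3 schemes. Without 5xFAD 2 the count was 86, of which 78 were among the 176, and without WT 5 it was 110, of which 106 were. Astrocytes lay in 2 clusters, 1 and 8, and cluster 8 held 63.1, 62.4, 31.8 and 36.1% of the nuclei of 5xFAD 1 to 4 and 18.7, 30.3, 41.5, 14.5 and 18.0% of those of WT 1 to 5, so the sums mix the clusters in different parts. Gfap is among the genes that lead cluster 8, so these parts were not tested. Of 42 called named genes 30 stayed called with each library left out. Other splits of the libraries gave at most 92 genes.

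Among the fixed lists, 6 of 7 measured pan-reactive genes rose in astrocytes (median log2 1.955, camera adjusted p = 2.81e-48, 0.0036 with an estimated correlation). So did all 4 of the A1 list (8.88e-20 and 0.00278), and 5 of 6 complement genes (3.99e-33 and 0.00278). In UMIs per nucleus the complement members C1qa, C1qb and C1qc rose by 0.104, 0.0350 and 0.0288 in astrocytes and by 0.0704, 0.0246 and 0.0188 in granule neurons. Most of their rise was thus also found in granule neurons, which are taken as the background here and below. The transgene cassette list gave 5.35e-07 and 0.0148. The disease-associated astrocyte list of the study rose in 8 of 16 members, 10 when adjusted over the list alone (0.0121 with an estimated correlation). This is not independent evidence, since the list comes from the same study. Also up were 6 of 17 disease-associated microglia genes (estimated correlation 0.0164), 5 of 11 disease-associated oligodendrocyte genes (0.0148), 2 of 3 microglia markers (0.0164) and 2 of 5 interferon genes (0.0485). Cholesterol synthesis fell in 2 of 14 genes, Msmo1 among them, or in 7 adjusted over the list alone. All 14 were negative with a median of -0.52, but the camera adjusted p of 8.76e-10 became an adjusted p = 0.119 with an estimated correlation. The lysosome list rose in 3 of 16 genes (7 over the list alone, all 16 positive, 3.85e-07, adjusted p = 0.148 with an estimated correlation) and MHC1 in 2 of 5 (0.00192, adjusted p = 0.178 with an estimated correlation). Neuron markers rose in 3 of 8 (0.00049, adjusted p = 0.276 with an estimated correlation) and homeostatic microglia genes in 1 of 5 (0.00928, adjusted p = 0.124 with an estimated correlation). Oligodendrocyte markers (0 of 6 called, 3 up over the list alone, 0.00148) and nuclear oxidative phosphorylation (0 of 14 called, median -0.20, 0.00928) had adjusted p = 0.18 and adjusted p = 0.427 with an estimated correlation. Homeostatic astrocyte genes fell in 1 of 18, Slc7a10 (camera adjusted p = 0.0704), and immediate early genes rose in 1 of 5, Fos (0.413). Myelin (10 measured, 0.295), synapse (17, 0.458), heat shock (6, 0.304), mitochondrial transcripts (8, 0.816), cytoplasmic ribosome (9, 0.304), nuclear long non-coding RNA (5, 0.304) and sex-linked genes (4, 0.243) held 0 called genes.

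More astrocyte nuclei had a UMI of the reactive genes in 5xFAD. After thinning to 600 UMIs, 76.7 ± 5.74% of 5xFAD nuclei had a Gfap UMI against 39.0 ± 9.93% in WT, 5.79 ± 3.03% against 0.491 ± 0.144% a Serpina3n UMI and 17.85 ± 7.53% against 6.34 ± 1.75% a Vim UMI (n = 4 and 5, exact 2-sided permutation, adjusted p = 0.00794, the smallest possible). In granule neurons, taken here as the background, the shares were 15.4 against 3.28% for Gfap, 0.668 against 0.137% for Serpina3n and 1.67 against 0.768% for Vim. Whether some of this rise lies inside the neurons stays open. Unthinned, astrocyte shares were 79.3 against 39.9% for Gfap, 7.855 against 0.722% for Serpina3n and 21.7 against 7.604% for Vim. The middle library had a median depth of 751.5 UMIs in 5xFAD and 661.0 in WT, and thinning left out 629 and 1152 nuclei with fewer UMIs.

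**Figure D1:**
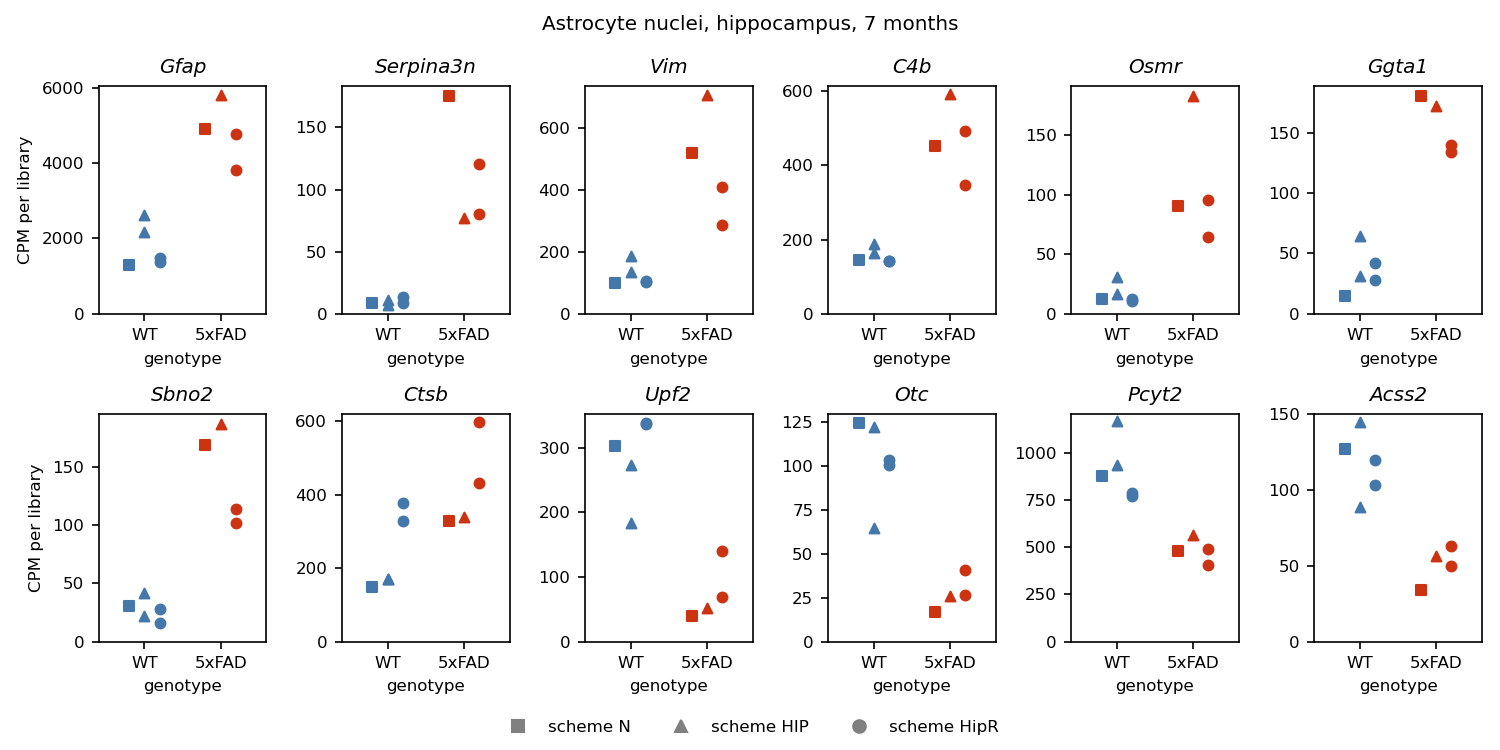
Counts per library of genes named for hippocampal astrocyte nuclei at 7 months. Each point is 1 library, by genotype and naming scheme.

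Microglia nuclei of 5xFAD carried more Ctsd, Trem2 and Apoe. Ctsd rose from 221 ± 159 to 836 ± 585 CPM (log2 1.74, SE 0.22, n = 5 and 4, edgeR adjusted p = 8.95e-07). Trem2, a lipid receptor, rose from 59.5 ± 25.4 to 264 ± 152 (1.99, SE 0.35, edgeR adjusted p = 0.00031) and Apoe by 0.82 (SE 0.15, edgeR adjusted p = 0.000881). The smallest adjusted p was that of 1700112E06Rik, 73.8 ± 25.2 to 461 ± 164 CPM (2.55, SE 0.28, edgeR adjusted p = 4.91e-08), and Fgf13, 216 ± 102 to 860 ± 504 (1.83, SE 0.23). Arhgap24 rose by 3.05 (SE 0.47, 6 against 96 counts), Myo1f by 1.50 (SE 0.24), Tgfbr2 by 1.71 (SE 0.31), Cd84 by 1.97 (SE 0.37) and Thy1 by 1.23 (SE 0.20). Gfap rose by 1.78 (SE 0.24), but its rise of 0.308 UMIs per nucleus was near that of the background, 0.259 in granule, 0.286 in pyramidal and 0.258 in inhibitory neurons. For Apoe the rise was 1.81 UMIs per microglia nucleus against 0.920, 0.915 and 0.935 in these neurons, for Ctsd 0.400 against 0.119, 0.141 and 0.118, and for Trem2 0.129 against 0.0238, 0.0231 and 0.0373. Within N, HIP and HipR the values were 3.14, 2.15, 2.66 for 1700112E06Rik, 1.09, 1.86, 1.80 for Ctsd, 1.86, 1.50, 2.31 for Trem2 and 1.03, 0.88, 0.71 for Apoe.

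Microglia nuclei had fewer transcripts of 4930578G10Rik, which fell by log2 -2.13 (SE 0.39, edgeR adjusted p = 0.000687). Gm12394 overlaps it on the other strand. Rwdd1 fell by -1.55 (edgeR adjusted p = 0.021, 0.103 without 5xFAD 3, 0.00383 to 1 over alternatives). Tyrobp rose by 1.33 (SE 0.32, edgeR adjusted p = 0.021, 0.234 without WT 5, 0.00505 to 0.903), Ank by 1.03 (0.0389, 0.385 without WT 4, 0.0104 to 0.903) and Neat1 by 1.26 (0.00994, 0.151 without WT 4, 0.0103 to 0.903). The homeostatic genes P2ry12, at log2 -0.19 (edgeR adjusted p = 0.889), and Cx3cr1, at -0.55 (0.589), did not pass, and App was at 0.06 (0.972). Cst7, Itgax, Clec7a and Tmem119 had too few counts to be tested. With edgeR 26 of 2900 genes changed, 24 up and 2 down, all 26 in the same direction within the schemes, 15 did with DESeq2 and 1 with no naming scheme term.

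Disease-associated microglia genes rose in 5 of 10 members in microglia (8 over the list alone, all positive, median log2 0.99, camera adjusted p = 5e-21, 0.00402 with an estimated correlation), and 2 of 8 of the study's own astrocyte list rose (7 over the list alone, 0.00402), again not independent evidence. Homeostatic microglia genes held 0 called of 8 (median -0.03, camera adjusted p = 0.452) and complement 0 of 5 (0.199). The lysosome list, 1 of 12 called (0.000601), and homeostatic astrocyte genes, 0 of 9 (0.0275), had adjusted p = 0.249 and adjusted p = 0.28 with an estimated correlation.

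Oligodendrocyte nuclei carried more C4b, 377 ± 134 to 1080 ± 312 CPM without overlap (log2 1.53, SE 0.23, n = 5 and 4, edgeR adjusted p = 1.47e-05), Gfap (1.97, SE 0.28, edgeR adjusted p = 1.19e-05, tested and called in 8 of 9 fits with a library left out) and Thy1 (1.72, SE 0.26). In UMIs per nucleus C4b rose by 0.337 against 0.0211 in granule neurons, but Gfap by 0.356 against 0.259 and Ctsd by 0.164 against 0.119, near the background. Ctsd rose by 1.36 (edgeR adjusted p = 0.00355, 0.173 without 5xFAD 3, 0.000794 to 0.999 over alternatives) and Zbtb16 by 1.38 (0.0485, 0.561 without WT 5, 0.00272 to 0.999). The myelin gene Cnp fell from 1606 ± 737 to 746 ± 402 CPM (-1.13, SE 0.23, edgeR adjusted p = 0.00355, 0.309 without WT 5, 2.92e-05 to 0.999), by -3.13, -0.64 and -1.02 within the schemes. The -3.13 rests on 5xFAD 1, with 22 oligodendrocyte nuclei and 22427 UMIs in all. Its Cnp was at 149.8 CPM, against 877.3 to 1027 in the other 5xFAD libraries. Upf2 fell by -1.31 (edgeR adjusted p = 0.042, 0.216 without 5xFAD 4, 0.000245 to 0.999). Mbp was at 0.02 (0.976 by edgeR, adjusted) and Il33 at 0.04 (0.969), and Serpina3n was not tested. Myelin genes fell in 1 of 12 (5 over the list alone, median -0.49, camera adjusted p = 1.17e-05, adjusted p = 0.212 with an estimated correlation), and disease-associated oligodendrocyte genes rose in 1 of 6 (camera adjusted p = 0.101). With edgeR 7 of 1292 genes changed, 0 with DESeq2, and without 5xFAD 1, WT 3 or WT 4 there were 14, 16 and 15.

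In oligodendrocyte precursors (n = 5 WT and 3 5xFAD, since 5xFAD 1 had 9 such nuclei) Gfap rose from 102 ± 90.8 to 871 ± 80.2 CPM (log2 2.44, SE 0.25, edgeR adjusted p = 3.68e-18) and C4b by 2.17 (SE 0.52, edgeR adjusted p = 0.0146, 0.00329 to 0.585 over alternatives), both without overlap. With a library left out C4b had enough counts to be tested in only 4 of 8 fits, and was called in these 4. Thy1 rose by 1.36 (1.95e-06 by edgeR, adjusted, 0.0897 without WT 5, 1.18e-06 to 0.979 over alternatives), Ctsd by 1.47 (6.75e-06, 0.0835 without WT 5, 5.7e-06 to 0.679), Aldoc by 0.87 (0.0239, 0.738 without WT 4, 0.0112 to 0.999) and Clu by 0.78 (0.0253, 0.738 without WT 4, 0.00538 to 0.999), and Ddx24 fell by -1.07 (0.0253, 0.35 without WT 5, 0.0177 to 0.998). In UMIs per precursor nucleus Gfap rose by 0.349, Ctsd by 0.228, Aldoc by 0.210, Clu by 0.266 and C4b by 0.0773, against 0.259, 0.119, 0.0960, 0.166 and 0.0211 in granule neurons. With edgeR 9 of 2785 genes changed and 2 with DESeq2, but 1 without WT 5 and 4 without WT 4 or 5xFAD 4. In endothelial nuclei 1 of 3449 genes changed, Gfap (1.56, SE 0.24, edgeR adjusted p = 0.00163, 0.0904 without 5xFAD 2, 7.53e-07 to 0.812 over alternatives), by 0.287 UMIs per nucleus and so near the background, and 30 of 100 splits, the real grouping included, gave as many genes.

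Granule neuron nuclei of 5xFAD carried more glial transcripts (n = 5 WT and 4 5xFAD). Gfap rose 5.09-fold, from 55.9 ± 24.3 to 286 ± 97.4 CPM (log2 2.35, SE 0.13, edgeR adjusted p = 1.54e-09). Trem2 rose 10.2-fold, from 2.03 ± 0.937 to 24.2 ± 5.58 (3.34, SE 0.28, edgeR adjusted p = 9e-07). Thy1 rose from 179 ± 45.7 to 485 ± 215 CPM (1.32, SE 0.13). C1qa rose by 2.21 (SE 0.18), Ctss by 2.30 (SE 0.20), Tyrobp by 2.86 (SE 0.30) and Fcer1g by 1.86 (SE 0.23). Smaller were the rises of C4b by 1.46 (SE 0.19), Ctsd by 1.57 (SE 0.16), H2-D1 by 1.63 (SE 0.21), Clu by 0.91 (SE 0.13) and Cst3 by 0.70 (SE 0.09). Cst7 had 3 counts in WT and 128 in 5xFAD, a ratio of 50.9 (counting interval 17.0 to 250.1). C1qc rose by 1.55, C1qb by 1.51 and Ctsz by 1.50.

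Slc25a51, a mitochondrial carrier gene, fell in granule neurons from 87.5 ± 21.4 to 28.5 ± 13.1 CPM (log2 -1.70, SE 0.21, edgeR adjusted p = 0.000143) and the antisense gene Gm15886 by -1.59 (SE 0.24, edgeR adjusted p = 0.00138), both without overlap. Within N, HIP and HipR Slc25a51 was at -1.48, -1.13 and -2.07 and Gm15886 at -1.72, -0.57 and -2.17. Among the 10 named calls that leaving out a library removed were Gabarapl2 at -0.83 (edgeR adjusted p = 0.0234, 0.278 without 5xFAD 3, 2.72e-07 to 0.997 over alternatives), and Schip1 at -1.43 (0.0265, 0.141 without WT 5, 3.3e-05 to 0.491). Others of the 10 were Nrn1 at -0.57 (edgeR adjusted p = 0.0284, 0.149 without 5xFAD 4, 0.00767 to 0.999), Vim at 1.11 (0.0312, 0.321 without 5xFAD 3, 8.45e-05 to 0.999) and B2m at 0.78 (0.00589, 0.0996 without WT 4, 0.000115 to 0.999). App was at -0.03 (edgeR adjusted p = 0.963).

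With edgeR 34 of 10100 genes changed in granule neurons, 27 up and 7 down, all 34 in the same direction within the schemes, 31 changed with DESeq2 and 6 with no naming scheme term. Without 5xFAD 1 the count was 55 (33 of the 34 among them) and without WT 4 it was 22 (21 among them). All 5 measured complement genes rose (camera adjusted p = 5.59e-43, 0.000697 with an estimated correlation), 6 of 15 disease-associated microglia genes (0.000697), 2 of 3 pan-reactive genes (0.00099), 3 of 17 lysosome genes (0.00241) and 1 of 11 myelin genes (0.0444). The study's astrocyte list, not independent evidence, rose in 6 of 13. Synapse genes held 0 called of 18 (camera adjusted p = 0.472). Immediate early genes, 0 called of 4 with all negative (median log2 -0.36, 0.0128), and oxidative phosphorylation, 0 of 14 (-0.12, 0.0289), had adjusted p = 0.191 and adjusted p = 0.455 with an estimated correlation.

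Pyramidal neuron nuclei gave a similar set of genes. Gfap rose 5.38-fold, from 32.7 ± 12.7 to 184 ± 75.8 CPM (log2 2.43, SE 0.14, n = 5 and 4, edgeR adjusted p = 1.13e-07). Tyrobp rose by 3.25 (SE 0.19), Trem2 by 3.21 (SE 0.31), C1qa by 2.05 (SE 0.18) and Lyz2 by 2.82 (SE 0.32). Ctsz rose by 1.76 (SE 0.22), Ctsd by 1.47 (SE 0.18), Thy1 by 1.49 (SE 0.19) and Neat1 by 1.05 (SE 0.15). Alad, of haem synthesis, rose from 13.6 ± 3.82 to 33.5 ± 2.71 CPM without overlap (1.36, SE 0.16, edgeR adjusted p = 0.000526). Cst7 had 2 counts in WT and 166 in 5xFAD, a ratio of 84.7 (counting interval 23.1 to 705.5). Without overlap Gm15886 fell by -1.68 (SE 0.18), Schip1 by -1.09 (SE 0.15), Fam177a by -1.08 (SE 0.15) and Upf2 from 167 ± 38.1 to 90.8 ± 22.8 CPM (-0.93, SE 0.14, edgeR adjusted p = 0.00378). Slc25a51 fell from 84.7 ± 19.1 to 29.2 ± 20 CPM (-1.71, SE 0.25), by -0.54, -1.72 and -2.28 within the schemes.

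Among the 12 named calls in pyramidal neurons that depended on a library were C4b at log2 1.28 (edgeR adjusted p = 0.0146, 0.101 without WT 4, 0.000851 to 0.597 over alternatives), Clu at 0.67 (0.00548, 0.0645 without WT 4, 0.000108 to 0.999). Among them too were B2m at 0.88 (edgeR adjusted p = 0.00333, 0.0627 without WT 4, 0.000689 to 0.999), C1qb at 1.49 (0.00911, 0.116 without WT 4, 0.00159 to 0.784), and Vim at 1.22 (0.0125, 0.118 without WT 4, 0.00534 to 0.999). Others of the 12 were Nsdhl at 1.23 (edgeR adjusted p = 0.0269, 0.149 without 5xFAD 2, 0.00485 to 0.435) and Rpgrip1 at -1.53 (0.0268, 0.199 without WT 5, 0.000958 to 0.753). With edgeR 37 of 11169 genes changed, 30 up and 7 down, 36 in the same direction within the schemes, 46 with DESeq2 and 5 with no naming scheme term. The count was 67 without WT 1 or without 5xFAD 1 (all 37 among them each time) and 24 without WT 4 (22 among them). Complement rose in 5 of 5 (camera adjusted p = 1.48e-34, 0.00849 with an estimated correlation), disease-associated microglia genes in 7 of 16 (0.00849) and lysosome genes in 4 of 18 (0.0227). The 15 cholesterol genes were all positive, 1 called (median 0.39, 1.12e-10, adjusted p = 0.0727 with an estimated correlation). Immediate early genes held 0 called of 9, 7 down over the list alone (median -0.59, 4.23e-09, adjusted p = 0.0764 with an estimated correlation), and synapse genes 0 of 18 (0.383).

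In inhibitory neurons Gfap rose 4.87-fold, from 38.5 ± 15.5 to 194 ± 81.3 CPM (log2 2.28, SE 0.16, n = 5 and 4, edgeR adjusted p = 6.31e-10). C1qa rose by 2.30 (SE 0.24), Tyrobp by 2.99 (SE 0.32), Trem2 by 3.57 (SE 0.44, 8 against 96 counts), Thy1 by 1.05 (SE 0.13) and Ctsd by 0.94 (SE 0.15). Alad rose from 13.65 ± 7.54 to 47.8 ± 7.97 CPM (1.92, SE 0.26, edgeR adjusted p = 0.000146). Slc25a51 fell from 81.9 ± 18.4 to 27.2 ± 13.2 CPM (-1.65, SE 0.19, edgeR adjusted p = 1.29e-05) and Upf2 from 149 ± 28.5 to 80.1 ± 24.9 (-0.94, SE 0.16), both without overlap. Gm15886 was called at -1.52 (edgeR adjusted p = 0.0197, 0.286 without WT 5, 0.00152 to 0.999 over alternatives) and C4b at 1.75 (0.00427, 0.0951 without WT 5, 0.00187 to 0.772). Apoe was called at 0.70 (edgeR adjusted p = 0.0043, 0.0604 without 5xFAD 2, 0.000372 to 0.999) and Ctss at 1.61 (0.00434, 0.177 without 5xFAD 3, 0.000416 to 0.772). With edgeR 17 of 9749 genes changed, 14 up and 3 down, all 17 in the same direction within the schemes, 13 with DESeq2 and 3 with no naming scheme term. The count was 26 without WT 1 or 5xFAD 1 (all 17 among them) and 11 without WT 5 (all 11 among the 17). Disease-associated microglia genes rose in 4 of 15 (camera adjusted p = 5.81e-20, 0.00405 with an estimated correlation), and synapse genes held 0 called of 18 (0.698). Immediate early genes, 0 of 6 called and 3 down over the list alone, had a median of -0.67 (7.3e-06, adjusted p = 0.0902 with an estimated correlation).

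Across the 8 classes 35 of 222 called genes were called in more than 1 class. Gfap was called in 8 classes, Ctsd and Thy1 in 7, C4b in 6, Trem2 and Tyrobp in 5, and Apoe, C1qa, Ctss, Gm15886 and Upf2 in 4.

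**Figure D2:**
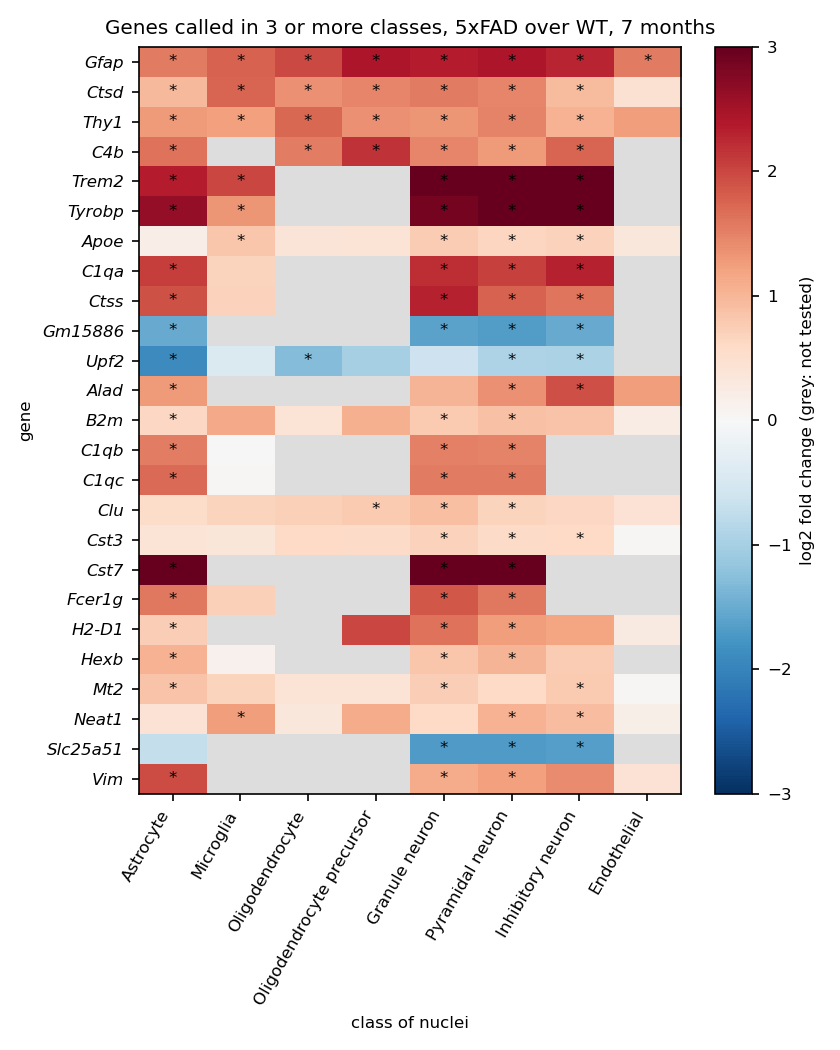
Log2 differences, 5xFAD minus WT, of genes called in 3 or more classes of nuclei at 7 months. Stars mark calls and grey marks genes not tested.

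Microglia made up 2.95 ± 0.26% of nuclei in 5xFAD and 1.42 ± 0.43% in WT, a difference of 1.53 points without overlap (n = 4 and 5, exact 2-sided permutation p = 0.00794, the smallest possible, adjusted 0.0873), and within N, HIP and HipR of 1.11, 1.73 and 1.71 points. Fibroblasts made up 0.607 ± 0.192% against 1.603 ± 0.601% (-0.996 points, exact p = 0.0159, adjusted 0.0873). After adjustment no class passed, and over 11 classes 1 class alone at the smallest possible p adjusts to 0.0873, so none could have passed alone. Astrocytes were at 12.7% in 5xFAD against 13.97% in WT (exact p = 0.667). Granule neurons were at 23.3 against 25.8%, pyramidal neurons at 25.3 against 23.9%, and inhibitory neurons at 9.43 against 9.36%. Oligodendrocytes were at 1.52 against 1.59%, precursors at 1.79 against 2.58%, endothelial nuclei at 2.57 against 1.62% and ependymal nuclei at 1.26 against 2.15%.

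**Figure D3:**
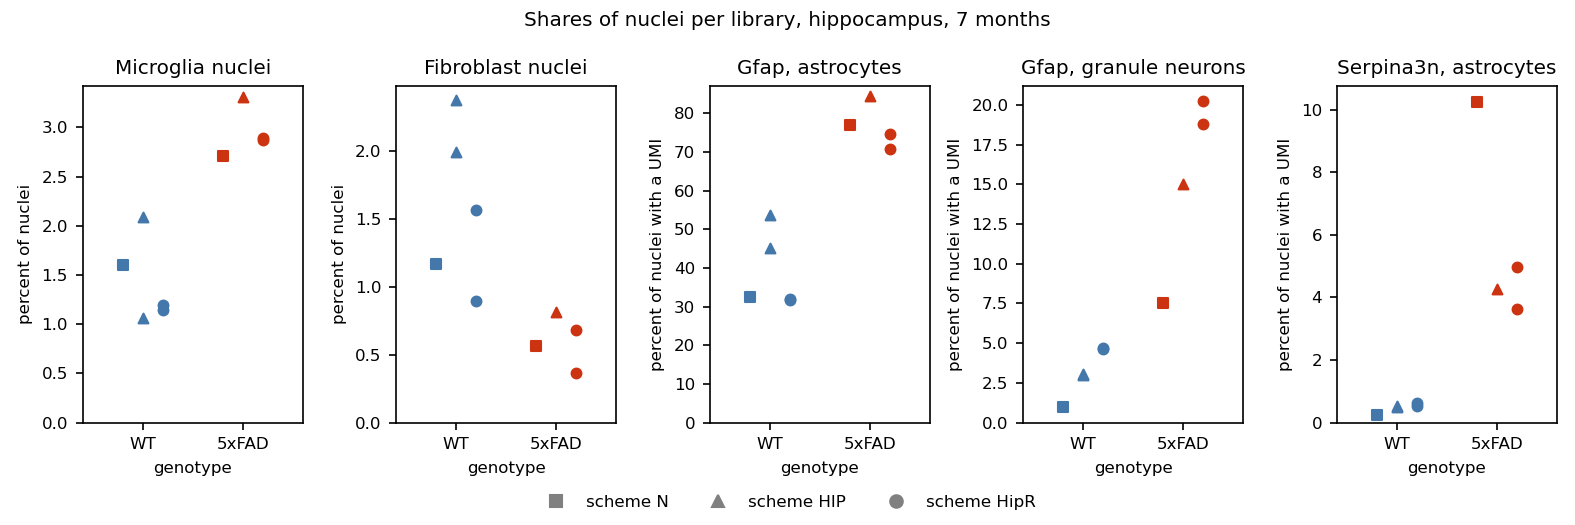
Percent of nuclei that are microglia or fibroblasts, and percent of astrocyte or granule neuron nuclei with a UMI of Gfap or Serpina3n after thinning, per library at 7 months.

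Over the astrocyte time course Gfap was 2.35-fold higher in 5xFAD as a mean of 5 age bins (log2 1.23, SE 0.13, n = 11 WT and 10 5xFAD libraries in these bins, with 2 WT libraries of 19.6 months in the fit, adjusted p = 1.61e-06). Osmr rose by log2 1.93 (SE 0.21) and Serpina3n 13.3-fold (3.73, SE 0.42, adjusted p = 1.89e-06). Also up were Thy1 by 1.56 (SE 0.17), Ggta1 by 1.71 (SE 0.21), C4b by 1.22 (SE 0.16, adjusted p = 2.08e-05), Sgcd by 1.58 (SE 0.20), Enox1 by 1.17 (SE 0.16) and Sbno2 by 1.49 (SE 0.23). Vim rose by 1.08 (adjusted p = 0.00788, 0.188 without 5xFAD 10 months, 8.35e-08 to 1 over alternatives), Ctsb by 0.69 (0.0191, 0.447 without 5xFAD 10 months, 0.00163 to 0.892). The interferon genes Ddx60 and Oasl2 rose, Ddx60 by 1.9981 (0.00788, 0.0684 without WT 7-8 months replicate 2, 0.000554 to 0.564) and Oasl2 by 3.48 (0.0204, 1 without 5xFAD 4-5 months replicate 2, 0.00174 to 1). Otc fell by -1.33 (SE 0.25, adjusted p = 0.00815, 0.705 without WT 7-8 months replicate 2, 1.51e-05 to 0.751) and St6galnac5 by -0.67 (0.0204, 1 without WT 10 months, 0.00164 to 1). Apoe was at 0.13 (adjusted p = 0.977), Clu at 0.49 (0.486), Cst3 at 0.44 (0.588), Slc1a2 at 0.19 (0.836) and Slc1a3 at 0.10 (0.947).

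With edgeR 38 of 11623 genes differed in that mean, 33 up and 5 down, and 7 with no naming scheme term. The count was 11 without WT 10 months or without 5xFAD 10 months, 67 and 60 without 5xFAD 13-14 months replicate 1 or 2, 16 without 5xFAD 4-5 months replicate 2, and 21 and 17 without WT 7-8 months replicate 1 or 2. Pan-reactive genes rose in 6 of 10 (camera adjusted p = 6.98e-35, 1.63e-05 with an estimated correlation), interferon genes in 3 of 14 (9 over the list alone, 0.0011), complement in 1 of 8 (4 over the list alone, 0.00251) and A1 genes in 1 of 7 (all 7 over the list alone, 0.000613). The A2 list held 0 called of 3 (0.0249, adjusted p = 0.0826 with an estimated correlation) and vessel markers 0 of 6 (0.92). Cholesterol synthesis held 0 called of 15, 1 positive (median log2 -0.16, 0.000531, adjusted p = 0.182 with an estimated correlation).

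At 1.5 months (n = 3 and 3) edgeR called 0 genes, with 164 at unadjusted p under 0.05, and DESeq2 called 0. Thy1 was at log2 1.27 (edgeR adjusted p = 0.224), Gfap at 0.18, Serpina3n at 0.30, Vim at -0.24 and C4b at 0.00. The transgene cassette list gave a camera adjusted p = 1.68e-08, or 0.00589 with an estimated correlation. At 4-5 months (n = 2 and 2) edgeR called 0, with 332 at unadjusted p under 0.05, and DESeq2 0. Osmr, picked here after its value was seen, was at 1.93 (SE 0.47), Thy1 at 1.33, Ggta1 at 1.10, Serpina3n at 1.05, Gfap at 0.84 and C4b at 0.82. Without 5xFAD 1.5 months replicate 2, or 5xFAD 13-14 months replicate 1 or 2, 1 gene was called at 1.5 months, and without WT 4-5 months replicate 1 there was 1 at 4-5 months.

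At 7-8 months (n = 2 and 2) edgeR called 7 genes, all up, and DESeq2 3. Serpina3n had 2 counts in WT and 93 in 5xFAD, a ratio of 22.5 (counting interval 6.06 to 188.7). Osmr rose by log2 2.51 (edgeR adjusted p = 0.0108, 4.54e-08 to 0.91 over alternatives), Gfap by 1.58 (0.0155, 1.05e-06 to 1), Ggta1 by 2.36 (0.0225, 1.24e-06 to 1), Enox1 by 2.14 (0.0108, 7.66e-06 to 1) and Thy1 by 1.9606 (0.0412, 0.000147 to 1). Without WT 7-8 months replicate 2 each of these genes had an adjusted p of 0.863, 0 genes were called without either WT library of this age, and 1 gene, not of the 7, was called without 5xFAD 7-8 months replicate 2. Pan-reactive genes rose in 3 of 10 (camera adjusted p = 7.22e-15, 0.000192 with an estimated correlation).

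At 13-14 months (n = 3 and 2) Osmr rose by log2 2.86 (SE 0.32, edgeR adjusted p = 7.32e-06), Serpina3n by 3.54 (SE 0.43) and C4b by 2.22 (SE 0.28). C3, the central complement gene, rose by 3.76 (SE 0.50, edgeR adjusted p = 5.82e-05), Gfap by 1.71 (SE 0.26), Thy1 by 1.93 (SE 0.28), Sgcd by 2.11, Ggta1 by 1.94 and S100a6 by 1.82. Aspg rose by 2.22 (edgeR adjusted p = 0.00223, 0.0615 without WT replicate 2, 3.35e-05 to 0.0954 over alternatives) and S1pr3 by 3.18 (0.00466, 0.071 without WT replicate 1, 3.41e-05 to 1). Tyrobp rose by 2.94 (edgeR adjusted p = 0.0104, 0.136 without WT replicate 2, 2.1e-06 to 0.631) and Vim by 1.64 (0.021, 0.165 without 5xFAD replicate 1, 6.7e-06 to 1). Cst7 had 0 counts in WT and 54 in 5xFAD, at least 22.3-fold (edgeR adjusted p = 0.0116, 0.123 without WT replicate 2, 4.28e-06 to 0.297). The time course held no other class of nuclei, so background could not be set apart for Tyrobp and Cst7. Otc fell by -2.11 (edgeR adjusted p = 0.035, 0.37 without WT replicate 1, 0.000347 to 0.852) and Slc7a10 by -1.0018 (0.0363, 0.262 without WT replicate 1, 0.00868 to 1). Apoe was at 0.13 (edgeR adjusted p = 1) and was called in the other direction, at -1.37, without 5xFAD replicate 1 (0.0125). With edgeR 38 genes changed, 36 up and 2 down, but 388 (28 of the 38 among them) without 5xFAD replicate 1, 17 without WT replicate 1 and 24 without WT replicate 4. Pan-reactive genes rose in 7 of 10 (camera adjusted p = 2.73e-32, 4.7e-06 with an estimated correlation) and complement in 2 of 8 (7 over the list alone, 0.000514).

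The 10-month pair had 1 library per genotype and no test, and its 95% intervals cover counting error only. Gfap was at 7698 CPM (7406 to 7998) in 5xFAD and 2129 (1928 to 2346) in WT, Vim at 725 (637.5 to 821) and 182 (127 to 253), C4b at 590.1 (511 to 677.5) and 187 (131 to 259), Serpina3n with 46 counts at 98.9 to 180.1 and with 0 at up to 19.2, and Ctsb at 390.5 (327 to 463) and 130.1 (84.2 to 192).

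With age, 508 of 11623 genes changed in 5xFAD astrocytes, 358 up and 150 down, and 15 in WT astrocytes, 12 up and 3 down (edgeR slopes as log2 per 10 months, n = 10 and 13). With no naming scheme term there were 6 and 4. For the difference in slope between genotypes 13 of 100 splits, the real grouping included, gave as many genes, so chance cannot be excluded for it. In 5xFAD C4b rose by 2.52 (SE 0.22, adjusted p = 3.52e-10), Osmr by 2.84 (SE 0.30), Serpina3n by 3.54 (SE 0.39), Aspg by 2.64 (SE 0.31), and Sgcd by 2.18 (SE 0.28). Plce1 rose by 1.53 (SE 0.20), C3 by 2.73 (SE 0.37), Dpyd by 1.62, Ggta1 by 2.00 (SE 0.28), and Gfap by 1.11 (SE 0.20). Vim rose by 1.32, Trem2 by 3.73 (SE 0.63), Ddx60 by 2.35 (SE 0.41), Ifit3 by 2.34 and H2-K1 by 1.20. For Trem2 background could not be set apart here either. Falling were Pcyt2 by -1.57 (SE 0.20, adjusted p = 1.09e-06), Otc by -2.57 (SE 0.32), Map2k6 by -1.26 (SE 0.20), and Sox8 by -1.21. Slco1c1 fell by -1.02, Fgfr2 by -1.09, Slmo1 by -1.11, Tnc by -1.38, and Fxyd6 by -1.62. Myoc fell by -1.41, Cyp51 by -1.39 (SE 0.29) and Msmo1 by -1.15 (SE 0.23). Nrg3 was called at 1.77 (adjusted p = 0.017) but at -0.14 without 5xFAD 13-14 months replicate 2 (0.967, 7.6e-17 to 0.967 over alternatives), and Kcnip4 at 1.77 (0.000311) but at 0.89 without it (0.22, 4.27e-19 to 0.22). The 5xFAD count was 207 and 230 without 5xFAD 1.5 months replicate 2 or 3, and 1098 and 162 without 5xFAD 13-14 months replicate 1 or 2.

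Cholesterol synthesis fell with age in 10 of 15 genes of 5xFAD astrocytes (12 over the list alone, median log2 -0.88, camera adjusted p = 1.78e-14, 0.0124 with an estimated correlation). In WT it held 0 called of 15, 9 down over the list alone (median -0.46, 1.31e-12, adjusted p = 0.134 with an estimated correlation). In 5xFAD pan-reactive genes rose in 8 of 10 (1.81e-06 with an estimated correlation), complement in 5 of 8 (6.17e-05), A1 in 5 of 7 (0.00259), interferon in 6 of 14 (0.00873) and A2 in 1 of 3 (0.0329), while MHC1, 3 of 9 called (5.43e-06), had adjusted p = 0.0659 with an estimated correlation.

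In WT astrocytes Otc fell by log2 -1.06 per 10 months (SE 0.17, n = 13, edgeR adjusted p = 0.00207), Cyp4f15 rose by 1.03 (SE 0.18) and Cped1 by 1.02 (SE 0.18), and PISD, a symbol that is uncertain in mouse, rose by 1.48 (SE 0.15, edgeR adjusted p = 4.49e-08) in WT and by 2.12 (SE 0.23) in 5xFAD. Grip1 fell by -0.97 (edgeR adjusted p = 0.00313, 0.0635 without WT 19.6 months replicate 2, 5.14e-06 to 0.553 over alternatives), Acat2 by -1.13 (0.00442, 0.0547 without WT 19.6 months replicate 2, 0.00129 to 0.248). Rps2 rose by 2.22 (edgeR adjusted p = 0.00327, 0.0675 without WT 1.5 months replicate 3, 3.76e-10 to 0.32) and Cdh19 by 1.03 (0.0109, 0.15 without WT 1.5 months replicate 2, 2.52e-11 to 0.288). C4b was at 0.61 (edgeR adjusted p = 0.123), Gfap at -0.19 (0.892), Vim at -0.31 (0.909) and Serpina3n at -0.10 (1). The WT count was 8 and 7 without WT 1.5 months replicate 2 or 3, 9 without WT 13-14 months replicate 2, 33 without 5xFAD 13-14 months replicate 2 and 24 without WT 4-5 months replicate 2.

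The genes of the 7-month astrocytes and of the time course overlapped, over 7890 genes in both. Of 136 genes up at 7 months 25 were among the 28 up in the time-course mean (0.483 expected by chance), 28 among the 28 up at 13-14 months (0.483), and 81 among the 278 rising with age in 5xFAD (4.792). The genes shared at 13-14 months include Trem2, Tyrobp, Cst7, B2m and Thy1. At 7 months these rose less than 3 times as much in astrocytes as in granule neurons. Gfap, Serpina3n, Vim, C4b, Ggta1 and Osmr, shared as well, rose more than that. Background common to both data sets was not taken out of these overlaps. Of the 176 genes 95.45% had the same sign in the time-course mean. In 10 matched sets thinned to 600 UMIs, 61.6% of 5xFAD astrocytes had a Gfap UMI against 38.4% in WT (23.2 points, 9 of 10 sets, exact 2-sided sign-flip p = 0.00391, adjusted 0.00586, smallest possible 0.00195), and 3.86 against 0.329% a Serpina3n UMI (9 of 10 sets), while Vim differed by 4.35 points (adjusted 0.0723). Unthinned, Gfap differed by 22.3 points. Over all 10 5xFAD and 13 WT libraries of the time course, thinning left out 2799 and 6348 nuclei (37.4 and 58.1%). The middle median depths of these libraries were 696.75 and 663.0 UMIs. The WT values thus also cover libraries outside the matched sets, which were not in the test. Granule neurons were not part of this table.

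**Figure D4:**
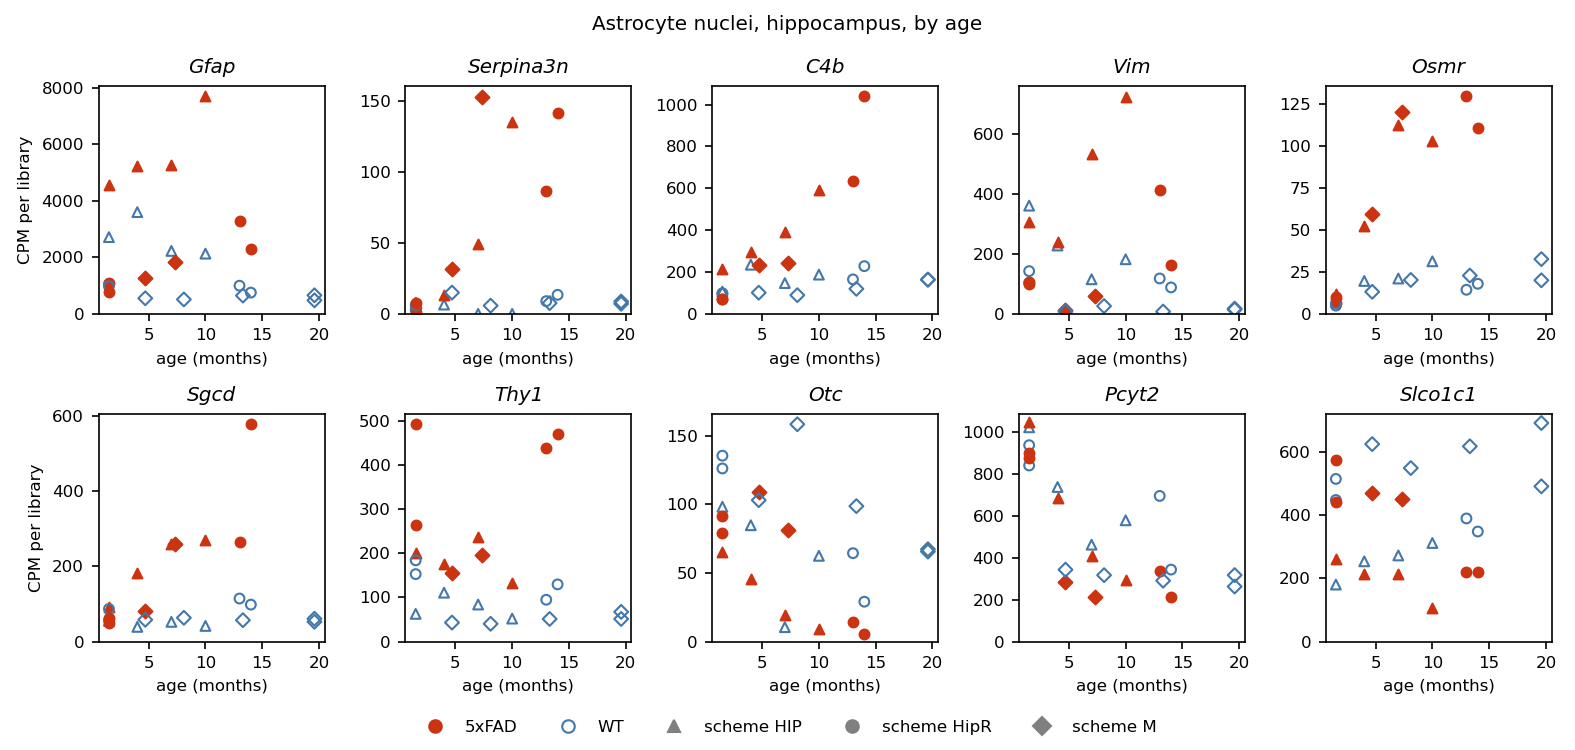
Astrocyte genes over age in WT and 5xFAD, each point 1 library.

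In cortex astrocytes (n = 2 and 2) edgeR called 0 of 9196 genes, with 184 at unadjusted p under 0.05, and DESeq2 called 0. Gfap was at log2 1.91 (SE 0.71, edgeR adjusted p = 1), C4b at 1.34 (SE 0.39) and H2-D1 at 1.86 (SE 0.39). B2m was at 1.34, Clu at 1.09, Ctsb at 1.09, Fkbp5 at 1.19, Thy1 at 0.87, Vim at 1.65, Apoe at 0.71, Cst3 at 0.85, Slc1a2 at 0.20 and Slc1a3 at 0.07. The libraries were of 7 and 10 months, 1 per genotype each, and the fit held genotype alone. With age as a block edgeR called 0 genes too (Gfap 1.71, adjusted p = 0.161, Vim 1.50, adjusted p = 0.393). Thinning to 600 UMIs keeps only 62 nuclei of WT 1 and leaves out 1846, so 300 UMIs, an alternative chosen later, are used here. Then 17.8% of 5xFAD nuclei had a Gfap UMI against 8.52% in WT at 7 months and 54.3 against 17.8% at 10 months, and 1.52 against 0.923% and 8.46 against 3.12% a Vim UMI. This left out 117 5xFAD and 605 WT nuclei at 7 months and 168 and 70 at 10 months. Without 5xFAD 1 edgeR called 47 genes, without 5xFAD 2 it called 4 (Gfap 0.47, Vim -0.18) and without WT 1 it called 1. Each of these fits leaves 1 library in a group, so its spread comes from the other group alone and genotype mixes with age. The A1 list (4 of 4 over the list alone, camera adjusted p = 1.3e-12), complement (3 of 4, 2.42e-08) and interferon genes (3 of 7, 7.39e-09) had adjusted p = 0.383 with an estimated correlation.

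Cortex astrocytes differed from hippocampal astrocytes of the same 4 mice in 145 of 8064 genes, 110 up and 35 down, and in 67 with DESeq2. Each region came from its own table with its own naming scheme. Median depths per library were 337.0 to 524.5 UMIs in cortex and 664.0 to 732.5 in hippocampus. The term for the animal does not remove these differences, so region cannot be told apart from table, naming scheme and depth. Higher in cortex were Gm20642 (log2 3.68, SE 0.38, edgeR adjusted p = 0.0004), Adarb2 (3.14, SE 0.33) and Gabbr2 (2.59, SE 0.32). So were Lrfn5 (2.58, SE 0.30), Fam19a2 (2.52, SE 0.39), Cntnap5a (2.44, SE 0.34), Lingo2 (2.44, SE 0.31), Lrrc7 (2.43, SE 0.30) and Nrg3 (2.19, SE 0.35). Grin2a was at 2.38 (edgeR adjusted p = 0.0131, 0.079 without the 7-month WT mouse, 6.37e-16 to 0.299 over alternatives) and Grin1 at 1.69 (0.0101, 0.0705 without the 10-month WT mouse, 6.79e-06 to 0.0705). Lower in cortex were Myoc, from 612 ± 68.2 to 263 ± 86.2 CPM (-1.21, SE 0.21, n = 4 and 4, edgeR adjusted p = 0.0088), and Gfap (-1.55, SE 0.28, edgeR adjusted p = 0.0114, 0.0826 without the 7-month WT mouse, 2.04e-12 to 0.207). So were Vim (-1.51, edgeR adjusted p = 0.0195, 0.0976 without the 7-month WT mouse, 3.23e-11 to 0.317), Gsn (-1.08, 0.0157, 0.0719 without the 7-month WT mouse, 3.58e-05 to 0.0719), and further Serpinf1 (-1.03, 0.0279, 0.0854 without the 10-month WT mouse, 0.000185 to 0.232) and Aqp4 (-0.90, 0.0335, 0.107 without the 10-month WT mouse, 0.000147 to 0.207).

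Between regions Apoe was at log2 -0.88 (edgeR adjusted p = 0.0838), C4b at -0.50 (0.176), Cst3 at -0.65 (0.181), Slc1a2 at -0.07 and Slc1a3 at -0.00. The count was 48 without the 7-month WT mouse and 49 without the 10-month WT mouse. Neuron markers were higher in cortex in 6 of 8 (median 1.19, camera adjusted p = 2.27e-14) and synapse genes in 5 of 16 (3.87e-11), pan-reactive genes were lower in 3 of 7 (4.78e-10) and the study's own astrocyte list, not independent evidence, in 8 of 15 (2.48e-23), each with adjusted p = 0.134 with an estimated correlation. For the difference in genotype effect between regions edgeR called 0 genes, with 133 at unadjusted p under 0.05, and DESeq2 called 0 (Gfap 0.25, SE 0.60, C4b -0.15, Clu 0.15). Without the 10-month 5xFAD mouse 1 gene was called.

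**Figure D5:**
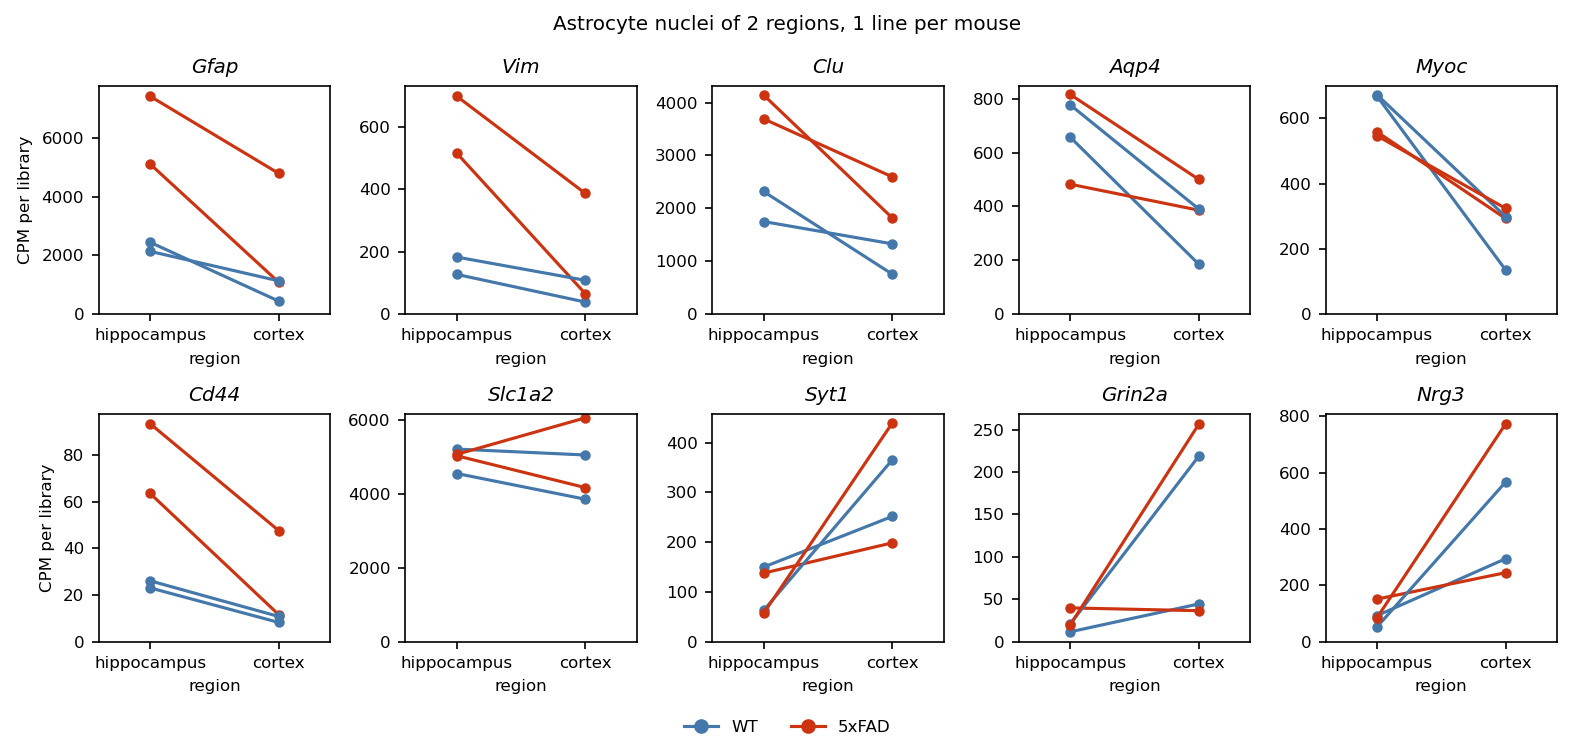
Astrocyte genes in hippocampus and cortex, 1 line per mouse.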

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

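The splits over all libraries were planned, while the splits within naming schemes and every other test of an explanation here were chosen after the result was seen.

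Glial transcripts were higher in 5xFAD granule neuron nuclei. Of the 27 genes that rose 17 were at least 3 times higher in astrocyte or microglia nuclei, 9 of them higher in microglia than in astrocytes. Of these 9, H2-D1 was far higher in endothelial nuclei (3.325 UMIs per 5xFAD nucleus, 0.150 in microglia). Free RNA in the droplets may account for this, since the same genes had like UMIs per nucleus in the other neuron classes (median absolute log2 ratio 0.1197). Nuclei caught together with microglia could not be told apart from this. The 14 other genes of 2 fixed microglia lists reached granule neurons at a median of 9.439% of their microglia level (1.633 to 64.545%). The 9 genes, H2-D1 included, reached them at a median of 23.752%. The comparison gave a log2 ratio of -1.3313 (bootstrap -2.1142 to 0.1465), and a range that wide leaves the question open. It replaced an earlier test that argued against such nuclei, whose genes had been chosen for a low level in astrocytes, which limits their level in other nuclei beforehand. Gfap in astrocytes is not covered by free RNA alone, since its 5xFAD minus WT difference in UMIs per nucleus was 10.0375 times that in granule neurons (8.6315 to 14.8697 with a library left out). Whether some of the genes changed inside neurons stays open.

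Genes higher in cortex than in hippocampal astrocytes were mostly genes of neurons, 98.182% of the 110 with a higher level in hippocampal neurons than in astrocytes against 38.765% of all tested genes, 59.4169 points more. RNA or nuclei of neurons among the cortex nuclei could give this, and the neuron marker list had a median of log2 1.1928. Dilution by such RNA does not account for the genes lower in cortex, since 18 homeostatic astrocyte genes had a median of log2 -0.045 (bootstrap -0.27 to 0.2888) against -0.9204 for the genes called lower. A regional difference in astrocytes themselves stays open for the genes called higher. For the genes called lower as well, it cannot be told apart from a difference of table, naming scheme or depth.

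Genes lower in 5xFAD in more than 1 class were Upf2 and Gm15886 in 4 classes, Slc25a51 in 3, and Schip1 and Fam177a in 2. Schip1 was not measured in the time course. The other 4 had a median of log2 -1.3436 at 7 months, each taken over the classes that called the gene. In the time course, which holds astrocytes only, it was -0.1845 over the last 2 age bins with more than 1 library per genotype. The values there, with intervals, were Gm15886 -0.99 (-1.74 to -0.24) and Slc25a51 -0.11 (-0.78 to 0.56). Those of Upf2 and Fam177a were -0.26 (-0.98 to 0.46) and 0.09 (-0.64 to 0.82). Slc25a51 was called in neurons only, so its comparison mixes classes. Within the schemes of 7-month astrocytes Upf2 was at -2.94, -2.15 and -1.69, each below its time-course interval. The interval of Gm15886 lies below 0. A consequence of the transgenes in any animal and another cause could thus not be told apart. A single stretch of chromosome that differs between the groups does not hold them all, since they lie on chromosomes 2, 3, 4 and 12 with 0 pairs within 5 Mb. Of the 45 located genes lower in 1 class 4 lie within 5 Mb of these 5, against 0.9238 in a mean random set (0.0125 of sets had as many). They are Srp54b, 0.031 Mb from Fam177a, and 4930578G10Rik, Gm12394 and Vcp, which was picked for its place, 2.416 to 2.66 Mb from Slc25a51. Since 4930578G10Rik and Gm12394 overlap, the 4 are not separate evidence. Several separate stretches, such as 1 around Slc25a51, stay open. So does a difference between breeding lines, since WT and 5xFAD carry different strain labels.

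Chance gives a library standing apart in about 1 in 20 groups, and 28 of 713 groups of values had one where 35.6 were expected. Each library below is set against the others of its own genotype only, so highest and lowest hold within that genotype. In shares of nuclei, ependymal nuclei were highest in 5xFAD 2 (2.699%, others 0.628 to 0.958), precursors lowest in WT 3 (0.5087%, others 2.79 to 3.375) and unnamed nuclei highest in WT 3 (34.27%, others 9.676 to 14.83). In astrocytes Bst2 was highest in 5xFAD 4 (50.32 CPM, others 25.68 to 28.2) and Ifi27 lowest in 5xFAD 3 (308.3, others 383.6 to 395.5). Endothelial nuclei had Clu highest in WT 5 (424.4, others 138.8 to 221.4), Hsp90ab1 in WT 2 (3059, others 745.9 to 1300.0), Jun in WT 2 (1043, others 225.5 to 424.4) and Slc1a2 in WT 4 (519.9, others 224 to 293.5).

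Within the genotype again, inhibitory neurons had Alad highest in WT 2 (26.48 CPM, others 8.044 to 13.08), Jun in WT 4 (37.2, others 16.39 to 18.71) and Upf2 in 5xFAD 3 (117.4, others 64.97 to 69.88). Microglia had B2m highest in WT 4 (383.5, others 0 to 104.9), Fgf13 in WT 5 (392.6, others 136.3 to 209.2), Trem2 in WT 5 (103.3, others 37.07 to 52.43) and P2ry12 lowest in WT 3 (313.5, others 348.6 to 356.5). In oligodendrocytes Cnp was lowest in 5xFAD 1 (149.8, others 877.3 to 1027). Pyramidal neurons had Arc highest in 5xFAD 4 (46.62, others 25.11 to 27.67), Cst7 in WT 4 (0.4398, others 0), Neat1 in 5xFAD 2 (82.06, others 39.45 to 46.54), Schip1 in WT 1 (48.47, others 25.51 to 30.35) and Upf2 in 5xFAD 3 (124.7, others 76.34 to 82.52). They had C4b lowest in 5xFAD 1 (10.76, others 26.06 to 27.34), and Ifi27 (76.38, others 126.4 to 143.4) and Meg3 (19990, others 23060 to 23610) lowest in WT 1.

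The genotype difference of astrocytes at 7 to 14 months exceeded that at 1.5 months in 3 genes by edgeR, Enox1 at log2 2.13 (adjusted p = 0.0119, 0.152 without 5xFAD 1.5 months replicate 2, 3.63e-05 to 1 over alternatives), Gfap at 1.53 (0.0486, 0.342 without it, 1.05e-05 to 1) and Sgcd at 2.31 (0.0486, 0.342 without it, 1.07e-05 to 1). With the real grouping included 3 of 100 splits gave as many genes, the highest other 12. That is below the planned limit, but only among splits within age bins that ignore the naming scheme. Of the 3 genes 0 stayed called with each library left out, and 0 genes were called with no naming scheme term or without the M libraries. The 3 calls thus rest on single libraries and on the scheme term.

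The age slope differed between genotypes in 38 genes by edgeR, but 13 of 100 splits, the real grouping included, gave as many and 1 gave 432, which points to a structure of the samples, and chance cannot be excluded. Higher slopes in 5xFAD were those of C4b (log2 1.91 per 10 months), Serpina3n (3.64), Sgcd (2.00), Grm5 (1.93), Aspg (2.35), C3 (3.12), S100a6 (1.62), Gfap (1.30), Cpne8 (1.89), Shisa6 (1.59), Cxcl10 (6.21), Osmr (2.23), Ggta1 (1.85), B2m (1.35), Gsn (1.5956), Csmd1 (1.22) and Vim (1.62). Lower were those of Pcyt2 (-1.14), Cox11 (-1.42), Slco1c1 (-0.96), Fgfr2 (-0.99), Tcaim (-1.35), Alas2 (-3.04) and Fam13c (-0.98). Only C4b, Serpina3n, Grm5 and S100a6 stayed called with every library left out, and the count was 4 without 5xFAD 1.5 months replicate 3, 20 without replicate 2, 168 without 5xFAD 13-14 months replicate 1, 104 without WT 13-14 months replicate 2, 19 and 23 without WT 19.6 months replicate 1 or 2, and 22 without WT 4-5 months replicate 2.

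Splits of the 7-month libraries gave as many genes as the genotypes in 1 of 100 for astrocytes (at most 92 in any other), 2 of 100 for microglia (27), 4 of 100 for oligodendrocytes (15), 2 of 55 for precursors (10), 2 of 100 for granule neurons (59), 2 of 100 for pyramidal neurons (242) and 2 of 100 for inhibitory neurons (113), counting the real grouping. These were drawn over all libraries, whatever their naming scheme, although the fit holds the scheme. Splits that keep the number of 5xFAD libraries within each scheme gave as many genes in 1 of 36 for 4 classes. These were astrocytes (176 genes, at most 72 in any other), granule neurons (34, at most 24), pyramidal neurons (37, at most 19) and inhibitory neurons (17, at most 13). This is the smallest share that 36 splits can give, and it was not adjusted over classes. It argues against chance for these 4 classes only if WT 1 and WT 3 are separate animals, and they are likely parts of 1 mouse. For microglia (26, at most 27) and oligodendrocytes (7, at most 8) 2 of 36 splits gave as many, a share of 0.0556, so chance cannot be excluded there. It cannot for endothelial nuclei either (30 of 100, at most 5, and 11 of 36). For precursors (9, at most 10) the 18 splits within schemes were too few. Every count takes WT 1 and WT 3, of the same mouse number, as separate animals. Taken as 1 animal they stay together, which leaves fewer splits within schemes, too few to exclude chance for any class.

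In the 3 neuron classes the highest split over all libraries set 5xFAD 1, 5xFAD 2, WT 2 and WT 3 against the others. It holds all of HIP on 1 side and all of HipR on the other, so its count rests on 5xFAD 1 against WT 1 of scheme N, which also differ in genotype. In pyramidal and inhibitory neurons that count was several times the real one, which points to a structure of the samples, and what sets this pair apart was not tested. For the time-course mean of 38 genes 1 of 100 splits gave as many (at most 12 in any other), so chance was excluded among splits drawn within age bins, whatever the naming scheme. Too few splits existed at 1.5 months (10 of 10) and for the regions (1 of 8, 0 genes in any other).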

How the results depend on the processing

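The alternatives below were planned, except the removal of high Scrublet scores, the HipR, N and HIP subsets, the fits without the M libraries, with the 4 shared libraries or without 19.6 months, and thinning to 300 UMIs, which were chosen after the data were seen. Among the alternative values 485 were the same, 159 moved, 11 reversed and 1 was stronger. Scrublet at its automatic threshold marked only 27 nuclei (0.0512%), so the 5% of nuclei with the highest scores were removed instead.

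Without the filter on low counts the genes called were 290 in astrocytes, 5 in microglia, 15 in oligodendrocytes, 137 in granule neurons, 56 in pyramidal neurons and 10 in endothelial nuclei. In the time course they were 80 for the mean, 2 at 1.5 months, 3 at 4-5 months, 20 at 7-8 months, 121 at 13-14 months, 23 for late minus 1.5 months, 68 for the WT slope and 133 for the slope difference, and 18 in cortex and 410 between regions. DESeq2 called 117 in astrocytes, 15 in microglia, 0 in oligodendrocytes, 2 in precursors, 3 at 7-8 months, 6 for late minus 1.5 months and 67 between regions. RLE scaling gave 1 for late minus 1.5 months.

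With no naming scheme term the genes called fell to 30 in astrocytes, 1 in microglia, 0 in oligodendrocytes, 1 in precursors, 6 in granule, 5 in pyramidal and 3 in inhibitory neurons and 0 in endothelial nuclei. In the time course they were 7 for the mean, 0 at 7-8 months, 2 at 13-14 months, 0 for late minus 1.5 months, 4 for the WT slope, 6 for the 5xFAD slope and 0 for the slope difference, and Hes1 had a WT slope of log2 -0.19 against 0.92 with the term (adjusted p = 0.0243, 0.001 to 0.867 over alternatives).

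Only the N and HIP libraries gave 56 genes in astrocytes (48 of the 176 among them), 2 in microglia, 0 in oligodendrocytes, 0 in precursors, 16 in granule, 6 in pyramidal and 4 in inhibitory neurons and 0 in endothelial nuclei. Only the HipR libraries gave 11 in oligodendrocytes, 72 in granule, 79 in pyramidal and 39 in inhibitory neurons and 3 in endothelial nuclei. The replicate block by title tag gave 18 in oligodendrocytes and 3 in endothelial nuclei, although the numbers in titles do not pair samples (correlation 0.051). With the libraries of mouse 74 summed there were 4 in oligodendrocytes, 56 in pyramidal and 26 in inhibitory neurons. Removing the highest Scrublet scores gave 15 in oligodendrocytes and 3 in endothelial nuclei, and an inhibitory neuron share difference of -0.0235 points. At Leiden resolution 0.5 the pyramidal neuron share differed by -0.1784 points.

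The replicate block by matched set gave 67 for the time-course mean, 1 at 1.5 months, 1 at 4-5 months, 16 at 7-8 months, 83 at 13-14 months and 16 for late minus 1.5 months (correlation within sets -0.188 to 0.591). Without the M libraries there were 6 for the mean, 0 at 7-8 months, 9 at 13-14 months, 0 for late minus 1.5 months, 287 for the 5xFAD slope (282 of the 508 among them) and 3 for the slope difference. With the 4 shared libraries added there were 72 for the mean, 52 at 7-8 months and 11 for late minus 1.5 months. On log2 age there were 24 for the WT slope and 14 for the slope difference, and without 19.6 months 5 for the slope difference. With no replicate block there were 32 between regions. A correlation estimated per list left 87 gene set tests called.

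With 1 library left out the genes called ran from 86 to 212 in astrocytes, 5 to 16 in oligodendrocytes, 1 to 12 in precursors, 22 to 55 in granule, 24 to 67 in pyramidal and 11 to 26 in inhibitory neurons and 0 to 2 in endothelial nuclei. They ran from 11 to 67 for the time-course mean, 0 to 1 at 1.5 months, 0 to 1 at 4-5 months, 0 to 9 at 7-8 months, 17 to 388 at 13-14 months, 0 to 15 for late minus 1.5 months, 7 to 33 for the WT slope, 162 to 1098 for the 5xFAD slope, 4 to 168 for the slope difference, 0 to 47 in cortex, 48 to 190 between regions and 0 to 1 for region by genotype. Share differences in points ran from -2.86 (without WT 3) to 1.64 (without 5xFAD 1) for astrocytes, -0.912 (without 5xFAD 1) to 0.611 (without WT 1) for inhibitory neurons, -0.377 to 0.288 for oligodendrocytes, -0.341 (without WT 3) to 3.25 for pyramidal neurons and -1.41 (without 5xFAD 1) to 7.12 (without WT 3) for unnamed nuclei. The time-course share with a Vim UMI ran from 2.64 (without set 4) to 5.06 (without set 2). Apoe at 13-14 months ran from log2 -1.37 to 0.82, and the 5xFAD slope of Nrg3 from -0.14 to 2.27.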

Other observations

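The genes set side by side here were chosen after the results were seen.

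Clustering of the 7-month nuclei split astrocytes into a large cluster of 5318 nuclei, with Otc, C030018K13Rik and Slc7a10 among its leading genes, and a cluster of 2234 nuclei led by Myoc, Serpinf1, Ggta1, Aqp4, Aspg, Gfap and Tnc. Of the genes named for the larger cluster, Otc (log2 -1.72), Slc7a10 (-0.66) and C030018K13Rik (-0.89) fell in 5xFAD astrocytes. Of the 7 of the smaller, Ggta1 (2.1029), Aspg (2.23) and Gfap (1.56) rose, while Myoc was at -0.78, Tnc at -0.42, Serpinf1 at -0.19 and Aqp4 at -0.06 and did not pass. No fit was made within each cluster.

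Microglia fell into clusters of 606 and 509 nuclei that followed the naming schemes, the smaller holding 69 to 75% of the microglia of HipR libraries. The split thus also followed the EZ and NP40 tags of the column names. 2 pairs of genes lower in 5xFAD, chosen after the values were seen, are neighbours or overlap. Fam177a (ENSMUSG00000095595.2, chr12 55124469-55142104), lower in pyramidal neurons at log2 -1.08, lies beside Srp54b (ENSMUSG00000112449.1, chr12 55155104-55189573), lower in astrocytes at -1.0048. Gm12394 (ENSMUSG00000078722.2, chr4 42781928-42856771, minus strand), lower in astrocytes at -1.86, overlaps 4930578G10Rik (ENSMUSG00000054885.11, chr4 42735545-42846248, plus strand), lower in microglia at -2.13, so the source of reads in the overlap is uncertain.

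Positions of genes that carried the results, on GRCm38, were those of Gfap (ENSMUSG00000020932.14, chr11 102887336-102900912), Serpina3n (ENSMUSG00000021091.8, chr12 104406729-104414329), Vim (ENSMUSG00000026728.9, chr2 13573927-13582826), C4b (ENSMUSG00000073418.4, chr17 34728380-34743882), Osmr (ENSMUSG00000022146.12, chr15 6813577-6874969), Upf2 (ENSMUSG00000043241.14, chr2 5951469-6056703), Otc (ENSMUSG00000031173.13, chrX 10252305-10321024), Slc25a51 (ENSMUSG00000045973.18, chr4 45395923-45408766) and the antisense gene Gm15886 (ENSMUSG00000085754.7, chr3 103771952-103789402).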
